A study of Daphnia magna with 30 samples.

How the data were processed

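Whole-body total RNA of Daphnia magna neonates was measured 48 h after the start of exposure on 30 arrays of 1 colour (Cy3). Per the labels, each sample pooled at least 20 individuals, 500 ng of total RNA was labelled, and each group came from 3 independent experiments. The 10 groups of 3 arrays were the solvent control (DMF), methoprene at 125, 250 and 500 ppb (Mt125, Mt250, Mt500), fenoxycarb at 0.5, 1 and 2 ppb (Fx0.5, Fx1, Fx2) and epofenonane at 50, 100 and 200 ppb (Ep50, Ep100, Ep200). The replicate number in each title was taken as the number of the experiment.

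Per the file headers, the scanner files were made with Agilent Feature Extraction 9.5.1.1 and hold intensity values, among them a processed signal from which background and spatial trends had been removed, with no scaling between arrays. Other columns hold flags of 0 or 1 per spot, per the file headers, for saturation, for outliers and for signal well above background. The deposited series table holds log2 ratios. It was checked against the scanner files for 40190 probes and equals the log2 processed signal less a constant per array and less the mean of the 3 DMF arrays.

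The array design holds 43803 non-control probes and 1417 control spots. The probes are 50 bases (26510 probes) or 60 bases (17293 probes) long. Every probe description in the files reads unknown, and 0 probe identifiers occurred in the reference table of genes, so probes are named by their identifiers and no gene name, position or genome build can be given. The 43803 probes carry 38705 distinct sequences, of which 3923 are shared by more than 1 probe. The median absolute difference in log2 fold change between 1734 tested pairs of probes with 1 sequence was 0.07 to 0.09, depending on the group.

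The processed signal was taken to log2 and each array's 75th percentile over the non-control probes was subtracted. The 82 spots with an outlier flag, over all arrays, were left out as missing values. Probes were tested if they were well above background on all 3 arrays of at least 1 group, which left 24127 probes (55.1%) with 20984 distinct sequences. 1 of them had no value on the DMF arrays, so 24126 probes were tested against DMF. Signals are relative, and the number of arrays limits the precision: each group mean rests on 3 arrays.

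Differences were tested with limma 3.58.1 in R 4.3.3. All 30 arrays and 10 groups were fitted together, with no covariate, and the moderated test was adjusted by the Benjamini-Hochberg method over the probes of each of the 15 comparisons. A probe was called at an adjusted p below 0.05. The comparisons were the 9 doses against DMF, the trend over the 3 doses of each compound (the slope per doubling of dose, which is the contrast of the highest with the lowest dose divided by the number of doublings between them) and the 3 differences between compounds at their highest doses. Standard errors and intervals of 95% come from the same fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and Biopython 1.88 read the files and translated the probe sequences, and matplotlib 3.10.9 drew the plots.

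The comparisons, the tests, the filter, the alternatives apart from those named below as added, 22 gene lists and the rule for named probes were fixed before the data were examined. The gene lists could not be matched without gene names, and their tests were not run. The rule named, for each comparison, up to 2 called probes with the largest rise and up to 2 with the largest fall whose 3 arrays all lay on 1 side of the 3 arrays of the other group. Where no probe was called it named the 5 with the smallest p. Their values in the other comparisons are given with them. Several of the named probes share 1 sequence, as stated with each. Where the dimmer group was not well above background on all 3 arrays, a fold is given as a lower bound ("at least"), computed against the lowest signal that the same array recorded as well above background. The log2 fold changes of such probes come from the fit and are no bound. Where no fold is given, they too can rest on signals near background.

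In place of the gene lists, 24 patterns of conserved protein motifs were searched in the 6 reading frames of the probe sequences. They were written after the annotation columns were seen and before any test was run. 6 patterns matched no probe, and the 6 classes with at least 5 tested probes (ubiquitin, cuticle protein, collagen, thioredoxin, trypsin-like serine protease, carboxylesterase or lipase) were tested with camera in limma, at a preset correlation of 0.01 between probes and again with an estimated correlation. Patterns were also searched in the reversed probe sequences as a count by chance. For the collagen pattern, whose repeats read alike when reversed, it is no such count.

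Whether the experiment number pairs arrays of different groups was checked for each comparison as the correlation, over probes, of the deviations of same-numbered arrays from their group means, with a pair taken to hold above 0.1. All 3 pairs held in 11 of the 15 comparisons. For the Mt500 and DMF arrays the correlations were 0.804, 0.408 and 0.723. In the other 4 comparisons a pair failed: Mt250 against DMF (-0.134), Ep50 against DMF (-0.138), Ep100 against DMF (-0.063) and the trend of epofenonane (-0.068), each for experiment 2. For the 11 comparisons whose pairs held, counts with the experiment as a block are given beside the result where they moved by more than 1.5 times. For the other 4 they are given only with the effects of the processing.

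The file headers place the arrays on 8 slides scanned on 3 days. DMF shared its 3 slides with the fenoxycarb groups, Mt125 shared 3 slides with the epofenonane groups, and Mt250 and Mt500 shared 2 slides with each other. No slide holds DMF beside methoprene or epofenonane, so slide was fitted as a random block (consensus correlation 0.435) and scan day as a fixed block. The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter, a filter on all 30 arrays (18478 probes), the deposited series table, these 3 blocks, a fit with only the compared groups, and leaving out each array in turn. A fit without the 3 arrays that lay with another experiment on the first principal component was added after the components were seen.

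All 9 doses share the 3 DMF arrays, so the correlation of fold changes between compounds was set beside 100 simulated draws of unchanged groups that share 3 controls. The overlap of calls of Mt500 and Ep200, and opposite calls of Mt125 and Mt500 and of Fx2 and Ep200, are set beside the number that independent calls would give. That number takes no account of the shared controls, and other overlaps are given as counts alone. The fit was tested on simulated data: among 24098 probes of Mt500 and DMF, 200 were changed in each of 5 simulations. Of the changed probes, 13.1%, 54.9% and 87.0% were recovered at log2 changes of 0.5, 1 and 2, with 1 false call on average. With the experiment as a block these shares were 38.2%, 67.8% and 92.4%, with 6.2 false calls. The simulated noise was independent between probes, and every array had the mean effect of its experiment. Real arrays depart from both, so these shares and false calls need not hold for them.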

Results

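Daphnia magna is a freshwater crustacean in which juvenile hormone and its agonists act on development and on the sex of offspring. The series asked which transcripts respond in neonates to 3 such agonists. Methoprene is a terpenoid analogue of the hormone, fenoxycarb is a phenoxy carbamate, and epofenonane is an aromatic ether with an epoxide. DMF is the solvent and served as the control. Each of the 10 groups had 3 arrays, from 3 independent experiments. Group values below are means over 3 arrays unless an array is named or left out, or a scan day or experiment is named. Within a scan day, 1 or 2 arrays of 1 group were compared with 1 array of the other. Within an experiment each group has 1 array. The 75th percentile of processed signal ran from 47.3 (replicate 1 of Mt500) to 81.3 (replicate 1 of Fx1) intensity units, and 48.0% to 57.7% of the probes of an array were well above background. No spot was saturated (0 on all arrays). The mean 75th percentile was 59.7 ± 5.46 (SD, n = 3) for DMF, 50.3 ± 2.62 for Mt500, 63.4 ± 8.42 for Fx2 and 61.5 ± 7.10 for Ep200. Signals below are log2 values relative to the array's 75th percentile.

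Over the 24098 tested probes with no missing value, the first principal component held 38.8% of the variance. On it 27 of the 30 arrays lay on the side of their experiment and 27 on that of their scan day, which nearly coincide. The sides part experiment 1 from experiments 2 and 3 and do not part experiment 2 from 3. The median score was -76.5 for experiment 1 and 23.8 for experiments 2 and 3. Replicate 1 of Mt250 (25.1), replicate 2 of Ep50 (-88.2) and replicate 1 of Ep100 (33.4) lay on the side of another experiment. The second component held 22.8% of the variance. On it the 3 arrays of Mt500 and the 3 of Ep200 lay at one end, and Mt125 and the fenoxycarb groups at the other.

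**Figure D1:**
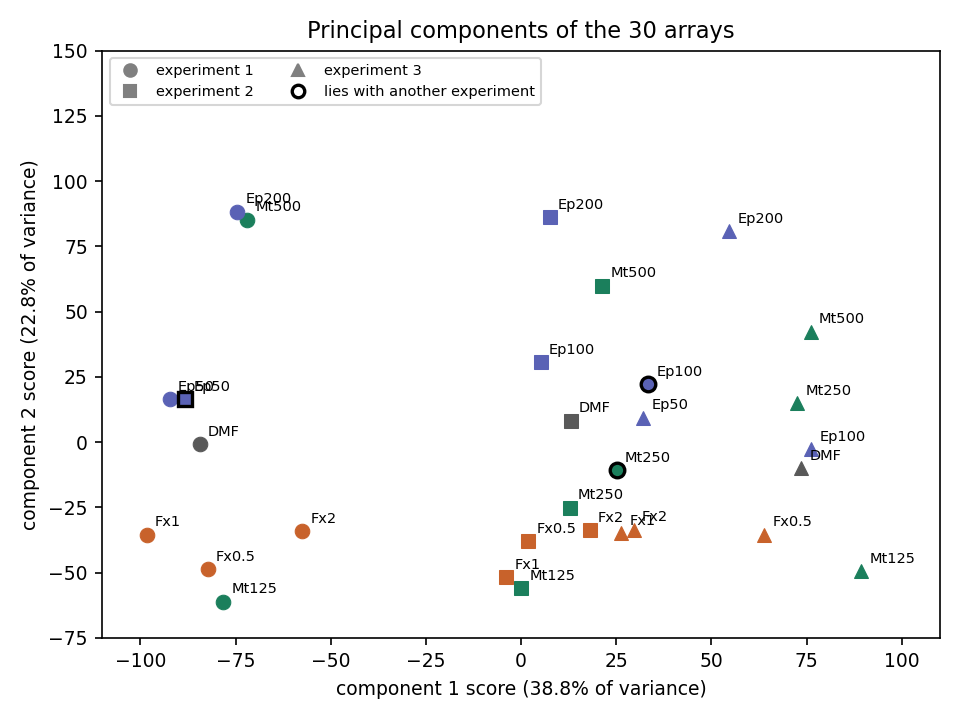
Scores of the 30 arrays on the first component (38.8% of variance, horizontal axis) and the second component (22.8%, vertical axis), with colour for the compound, shape for the experiment and black rims for the 3 arrays that lie with another experiment. Arrays of experiment 1 have a median of -76.5 on the first component.

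Methoprene at 125 ppb was compared with DMF to find the response to its lowest dose. Probe DM12614_1 rose most, from -4.84 ± 0.45 (SD, n = 3) in DMF to 3.11 ± 0.24 in Mt125, which is at least 78.4-fold (log2 fold change 7.95 ± 0.75 SE, adjusted p = 5.5e-07 by limma). Its sister probe DM12614_2 rose by 7.79 ± 0.89, at least 64.5-fold. DM09287_2, which has the sequence of DMAG0001S00005610, rose from 0.35 ± 0.49 to 6.35 ± 0.42 (adjusted p = 4.9e-11). Of the falling probes, DM05875_1 and DM05875_2 fell most, with log2 fold changes of -3.88 ± 0.47 and -3.75 ± 0.45. In all, 798 probes rose and 662 fell (6.1% of those tested), and 519 and 240 of them changed at least 2-fold. The calls covered 719 and 597 distinct sequences. With the experiment as a block, 3318 probes were called, with slide as a random block 1154 and with scan day as a block 3245. Within the 3 scan days the risen probes had median log2 differences of 1.48, 1.69 and 1.01 and the fallen probes -0.92, -0.87 and -0.67. Such medians are given below as sizes and are no test of scan day, since the probes were called on the same arrays. The total of 1460 fell to 970 and 674 without replicates 1 and 2 of DMF and to 853 and 762 without replicates 1 and 2 of Mt125. In a fit of the compared groups alone it was 727 (523 rose, 204 fell), and normexp background correction gave 1364 that rose and 450 that fell.

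At 250 ppb, DM12614_1 and DM12065_2 rose most, by 7.28 ± 0.75 and 7.18 ± 0.63 on the log2 scale, at least 49.5-fold and 45.8-fold. DM08568_1 rose to 2.57 ± 1.03 (SD, n = 3), by 5.58 ± 0.59 and at least 41.6-fold. DMAG0001S00001885, which has the sequence of DM02756_2, went from 1.06 ± 0.13 to -4.61 ± 0.42, a log2 fold change of -5.67 ± 0.45 (adjusted p = 3.8e-08), at least 18.0-fold lower. In all, 748 probes rose and 919 fell (6.9%), and 318 and 394 of them changed at least 2-fold. At both 125 and 250 ppb 300 probes rose and 455 fell, in calls that share the 3 DMF arrays. With slide as a random block 1125 probes were called and with scan day as a block 3538. All Mt250 arrays were scanned on days 2 and 3, within which the medians were 0.87 and 0.85 for the risen and -0.94 and -0.74 for the fallen probes. Without replicate 2 of DMF 952 probes were called, without the 3 arrays out of place 998 and with the compared groups alone 404. Normexp correction gave 771 that rose and 370 that fell.

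At 500 ppb, DM08568_1 rose most, to 3.50 ± 1.09 (SD, n = 3), a log2 fold change of 6.50 ± 0.59 and at least 78.9-fold (adjusted p = 1.1e-07). DM12065_2, with the sequence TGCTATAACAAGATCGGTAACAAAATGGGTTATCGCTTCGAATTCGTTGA, rose by 6.07 ± 0.63, at least 21.2-fold. DMAG0001S00001885 and DM02756_2, which share 1 sequence, fell most, with -5.75 ± 0.45 and -5.44 ± 0.50. DM05875_2 fell at this dose as well, from 4.98 ± 0.44 to 0.71 ± 0.09. In all, 2601 probes rose and 2317 fell (20.4%), of which 671 and 918 changed at least 2-fold, and 2320 and 2113 distinct sequences were covered. A block for the experiment called 7987 probes, with slide as a random block 3945 and with scan day as a block 7824. No Mt500 array was scanned on day 1, and within days 2 and 3 the medians were 0.69 and 0.69 for the risen and -0.74 and -0.90 for the fallen probes. The total of 4918 became 1222 with the compared groups alone and 2718 with normexp correction (1930 rose, 788 fell).

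**Figure D2:**
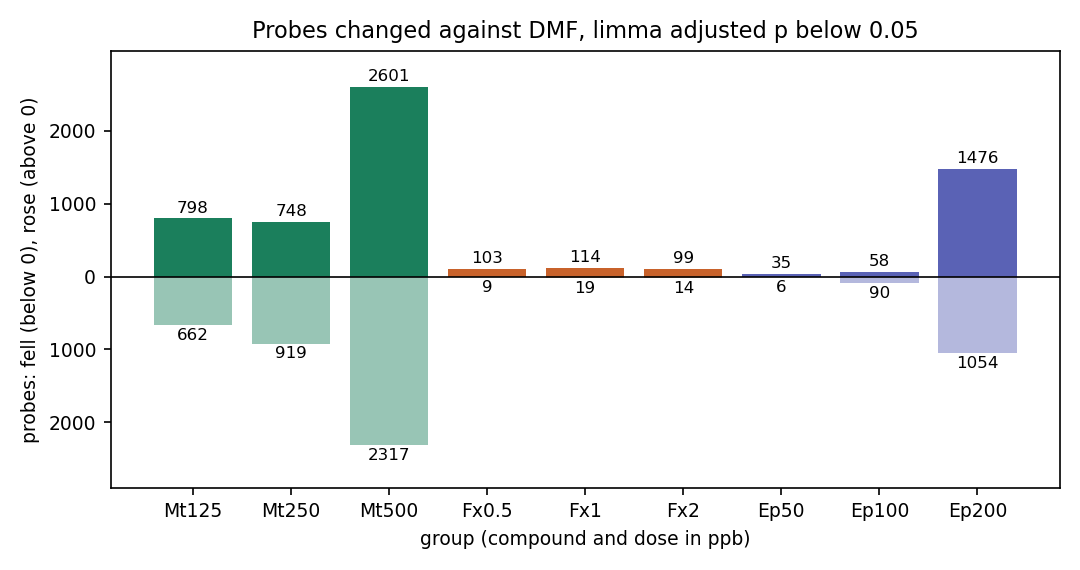
Number of probes that rose (bars above 0) and fell (bars below 0) against DMF at each dose, limma adjusted p below 0.05, for methoprene (green), fenoxycarb (orange) and epofenonane (blue). Mt500 had 2601 and 2317 and Ep200 had 1476 and 1054, while each fenoxycarb dose had 99 to 114 that rose.

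Over the 3 methoprene doses, 183 probes rose and 352 fell at every dose. Of the 183, 29 had a falling and 36 a rising slope over dose. DM12614_1 had a falling slope of -1.53 ± 0.37 per doubling (adjusted p = 0.0053), and DM09287_2 one of -0.81 ± 0.16 (adjusted p = 0.0009). The steepest rises over dose were those of DM07102_1, at 3.40 ± 0.59 per doubling, and DMAG0001S00003639, at 3.30 ± 0.57 (adjusted p = 0.00019). The steepest falls were those of DMAG0001S00004586 and DM07335_1, which share 1 sequence, at -3.71 ± 0.51 and -3.64 ± 0.49. DM07335_1 rose at 125 ppb (log2 fold change 4.08 ± 0.97, adjusted p = 0.013) and fell at 500 ppb (-3.20 ± 0.97, adjusted p = 0.022). It was 1 of 149 probes that rose at Mt125, fell at Mt500 and had a falling slope, beside 34 with the reverse. In all, 2258 probes had a rising and 2183 a falling slope (18.4%). Mt125 shared no slide with Mt500, so for this slope an effect of the slide cannot be told apart from one of the dose. The fit with the experiment as a block called 7306 probes, with slide as a random block 3720 and with scan day as a block 7290. Within days 2 and 3 the median slopes were 0.33 and 0.40 for rising and -0.54 and -0.52 for falling probes. The total of 4441 became 2306 with the compared groups alone and 2572 with normexp correction, and without a filter 4166 rose and 2230 fell.

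Fenoxycarb at 0.5 ppb was compared with DMF in arrays that lay on the same slides. DM10268_1 and DM10268_2, whose sequences overlap on 1 transcript number, rose most, by 3.92 ± 0.32 (adjusted p = 1.8e-07) and 3.88 ± 0.31, at least 8.06-fold and 9.60-fold. DM10268_1, with the sequence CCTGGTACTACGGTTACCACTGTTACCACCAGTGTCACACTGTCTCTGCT, went from -4.09 ± 0.38 in DMF to -0.17 ± 0.22 (SD, n = 3). DMAG0001S00001407 fell by 2.95 ± 0.58 (adjusted p = 0.016), at least 2.99-fold, and DM04941_2 fell by 2.69 ± 0.55 (adjusted p = 0.021), at least 1.70-fold. In all, 103 probes rose and 9 fell (0.5%), and 93 and 9 changed at least 2-fold. With the experiment as a block 235 probes were called, with slide as a random block 274 and with scan day as a block 227. The medians within the 3 days were 1.79, 1.73 and 1.57 for the risen probes. The total fell to 55 without replicate 2 of DMF and to 50 without replicate 1 of Fx0.5. It was 47 with the compared groups alone and 74 with the filter on all 30 arrays. DMAG0001S00001407 passed no longer without replicates 2 and 3 of DMF (adjusted p = 0.089 and 0.071) or replicates 1 and 3 of Fx0.5 (0.12 and 0.11), nor with the compared groups alone (0.11). DM04941_2 passed no longer without replicates 2 and 3 of DMF (0.17 and 0.077) or replicates 1, 2 and 3 of Fx0.5 (0.061, 0.097 and 0.1). Over all alternatives their adjusted p ran from 0.0021 to 0.12 and from 0.0016 to 0.17.

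At 1 ppb fenoxycarb, DMAG0001S00009369 and DM11876_1, which share 1 sequence, rose most, by 4.83 ± 0.84 (adjusted p = 0.0037) and 4.47 ± 0.89 (adjusted p = 0.015), at least 8.60-fold and 9.06-fold. DM10268_1 rose by 4.02 ± 0.32. DM15039_1 fell by 2.36 ± 0.41 (adjusted p = 0.0032), at least 1.31-fold, and DM05783_1 fell by 1.59 ± 0.28 (adjusted p = 0.0047), at least 2.08-fold. In all, 114 probes rose and 19 fell (0.6%), and 105 and 7 changed at least 2-fold. A block for the experiment called 449 probes (266 rose, 183 fell), with slide as a random block 524 (314 rose, 210 fell) and with scan day as a block 430 (265 rose, 165 fell). Within the 3 days the risen probes had medians of 1.63, 2.19 and 1.66. The total fell to 77 without replicate 2 of DMF and to 78 and 79 without replicates 1 and 2 of Fx1, and was 84 with the filter on all 30 arrays. DM11876_1 passed no longer without replicates 1 and 2 of DMF (adjusted p = 0.061 and 0.13) or of Fx1 (0.057 and 0.1). With normexp correction DMAG0001S00009369 (0.12), DM11876_1 (0.11) and DM15039_1 (0.071) did not pass, nor did DM05783_1 with the compared groups alone (0.39). Over all alternatives the adjusted p ran from 0.0012 to 0.12 for DMAG0001S00009369, from 0.0048 to 0.13 for DM11876_1, from 0.00032 to 0.071 for DM15039_1 and from 0.00029 to 0.39 for DM05783_1. With the compared groups alone 107 probes rose and 1 fell.

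At 2 ppb fenoxycarb, DM10268_1 rose to 0.09 ± 0.21 (SD, n = 3), a log2 fold change of 4.19 ± 0.32 and at least 9.71-fold (adjusted p = 5e-08), and DM10268_2 rose by 4.07 ± 0.31. DM07400_1 fell by 2.18 ± 0.48 (adjusted p = 0.041) and DMAG0001S00003115 fell by 2.03 ± 0.43 (adjusted p = 0.03). In all, 99 probes rose and 14 fell (0.5%), and 82 and 4 changed at least 2-fold. The same 79 probes rose at all 3 doses, with median log2 fold changes of 1.74, 1.83 and 1.82, and 1 probe fell at all 3. The fit with the experiment as a block called 241 probes (168 rose, 73 fell), with slide as a random block 336 (204 rose, 132 fell) and with scan day as a block 243 (169 rose, 74 fell). Medians within the 3 days were 1.61, 1.94 and 1.54 for the risen probes. The total fell to 68 without replicate 2 of DMF and to 69, 71 and 74 without replicates 1, 2 and 3 of Fx2. DM07400_1 passed no longer without replicates 1, 2 and 3 of DMF (adjusted p = 0.18, 0.23 and 0.054) or replicates 1 and 2 of Fx2 (0.058 and 0.33), nor without the 3 arrays out of place (0.081), without a filter (0.066), with normexp correction (0.059) or with the compared groups alone (0.32). DMAG0001S00003115 passed no longer without replicates 1 and 3 of DMF (0.19 and 0.084) or 2 and 3 of Fx2 (0.18 and 0.16), without the 3 arrays (0.067), without a filter (0.052) or with the compared groups alone (0.13). Over all alternatives their adjusted p ran from 0.011 to 0.33 and from 0.0027 to 0.19.

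Over the 3 fenoxycarb doses limma called 0 probes with a slope. At an unadjusted p below 0.05 there were 176 (0.7%), far under the share of 0.05 that would pass with no slope. The 3 Fx2 arrays all lay on 1 side of the 3 Fx0.5 arrays for 4.6% of probes, against 10% by chance. These p values therefore ran high, and a slope could be missed. Arrays of the same experiment went together in these groups (r = 0.808, 0.176 and 0.585), which the fit leaves out. With the experiment as a block 0 probes were called too. The probes with the smallest p were DMAG0001S00003610 (slope -0.55 ± 0.13 per doubling), DM01393_3 (-0.50 ± 0.13), DMAG0001S00002536 (0.20 ± 0.06), DM12832_2 (-0.17 ± 0.05) and DMAG0001S00000292 (-0.16 ± 0.05), and none passed (adjusted p near 1.0 for each). The slope of DM10268_1 was 0.13 ± 0.16, with a 95% interval from -0.20 to 0.47.

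Epofenonane at 50 ppb was compared with DMF for the response to its lowest dose. DM08568_1 rose by 2.92 ± 0.59 (adjusted p = 0.039), at least 6.61-fold, and DM01706_3 rose by 2.81 ± 0.45 (adjusted p = 0.004), at least 2.48-fold. DMAG0001S00007438 fell by 1.19 ± 0.22 (adjusted p = 0.02) and DM10219_1 fell from 1.74 ± 0.29 in DMF to 0.64 ± 0.44 (SD, n = 3, adjusted p = 0.022). DM10219_1 had risen in methoprene, by 1.14 ± 0.21 at 125 ppb. In all, 35 probes rose and 6 fell (0.2%), 28 and 3 of them at least 2-fold. Replicate 2 of Ep50 lay with experiment 1 on the first component, and without the 3 arrays out of place 19 probes rose and 0 fell. With slide as a random block 13 probes were called and with scan day as a block 120 (89 rose, 31 fell). The risen probes had medians of 1.19, 1.35 and 1.23 within the 3 days. The total fell to 20 and 24 without replicates 1 and 2 of DMF and to 18, 26 and 25 without replicates 1, 2 and 3 of Ep50, to 27 with normexp correction and to 0 by limma with the compared groups alone.

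The 4 named calls of Ep50 rested on single arrays and settings. The adjusted p of DM08568_1 was 0.1, 0.37 and 0.064 without replicates 1, 2 and 3 of DMF and 0.25, 0.067 and 0.21 without those of Ep50. It was 0.11 without the 3 arrays out of place, 0.7 with normexp correction, 0.065 without a filter, 0.058 with slide and 0.24 with the compared groups alone. For DM01706_3 it was 0.055 without replicate 1 of DMF, 0.072 without the 3 arrays, 0.74 with normexp correction, 0.052 with slide and 0.28 with the compared groups alone. For DMAG0001S00007438 it was 0.1 and 0.16 without replicates 1 and 2 of DMF, 0.13, 0.073 and 0.09 without those of Ep50, 0.072 without the 3 arrays, 0.2 with normexp correction, 0.18 with slide and 0.22 with the compared groups alone. For DM10219_1 it was 0.1 and 0.17 without replicates 1 and 3 of DMF, 0.24 and 0.13 without replicates 1 and 2 of Ep50, 0.22 without the 3 arrays and 0.76 with the compared groups alone. Over all alternatives the adjusted p ran from 0.00015 to 0.7 for DM08568_1, from 0.0027 to 0.74 for DM01706_3, from 0.015 to 0.22 for DMAG0001S00007438 and from 0.0021 to 0.76 for DM10219_1.

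At 100 ppb epofenonane, DMAG0001S00004436 rose most, by 3.38 ± 0.55 (adjusted p = 0.0027), at least 4.17-fold, and DM08568_1 rose by 2.67 ± 0.59 (adjusted p = 0.036). DM05875_1 and DM05875_2 fell by 2.27 ± 0.47 (adjusted p = 0.024) and 2.26 ± 0.45 (adjusted p = 0.017). In all, 58 probes rose and 90 fell (0.6%), 30 and 29 of them at least 2-fold. Replicate 1 of Ep100 lay apart from experiment 1 on the first component, and without the 3 arrays out of place 15 probes rose and 27 fell. With slide as a random block 83 probes were called and with scan day as a block 562. The fallen probes had medians of -0.85, -0.69 and -0.77 within the 3 days. The total fell to 60, 57 and 94 without replicates 1, 2 and 3 of DMF, to 62 and 80 without replicates 1 and 3 of Ep100 and to 0 by limma with the compared groups alone. Normexp correction gave 124 that rose and 35 that fell.

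Named calls of Ep100 ended as follows. DMAG0001S00004436 passed no longer with normexp correction (adjusted p = 0.17) or the compared groups alone (0.47). The adjusted p of DM08568_1 was 0.1, 0.23 and 0.055 without replicates 1, 2 and 3 of DMF, 0.16 and 0.18 without replicates 1 and 3 of Ep100, 0.22 without the 3 arrays, 0.31 with normexp correction, 0.064 without a filter and 0.39 with the compared groups alone. For DM05875_1 it was 0.055, 0.15 and 0.067 without replicates 1, 2 and 3 of DMF, 0.12 and 0.11 without replicates 1 and 2 of Ep100, 0.15 without the 3 arrays, 0.14 with slide and 0.32 with the compared groups alone. For DM05875_2 it was 0.12 and 0.056 without replicates 2 and 3 of DMF, 0.099 and 0.089 without replicates 1 and 2 of Ep100, 0.1 without the 3 arrays, 0.11 with slide and 0.32 with the compared groups alone. Over all alternatives it ran from 0.00012 to 0.47 for DMAG0001S00004436, from 0.0002 to 0.39 for DM08568_1, from 0.011 to 0.32 for DM05875_1 and from 0.0081 to 0.32 for DM05875_2.

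At 200 ppb epofenonane, DM08568_1 rose to 3.70 ± 0.33 (SD, n = 3), a log2 fold change of 6.70 ± 0.59 and at least 90.7-fold (adjusted p = 1.8e-07). DM07102_2 rose by 5.03 ± 1.14, at least 24.4-fold (adjusted p = 0.0052). DM07335_1 fell from 1.37 ± 0.78 to -5.18 ± 0.73, a log2 fold change of -6.55 ± 0.97, at least 23.4-fold lower (adjusted p = 9.9e-05), and DM07435_2 fell by 6.53 ± 0.65, at least 19.4-fold. DM12065_2 and DM12614_1, which rose at every methoprene dose, had log2 fold changes of 0.60 ± 0.63 and 0.11 ± 0.75 here and did not pass. In all, 1476 probes rose and 1054 fell (10.5%), 405 and 701 of them at least 2-fold, over 1324 and 963 distinct sequences. With the experiment as a block 4927 probes were called, with slide as a random block 2205 and with scan day as a block 4796. Within the 3 days the medians were 0.61, 0.66 and 0.70 for the risen and -1.27, -1.57 and -1.46 for the fallen probes. The total of 2530 became 1663 without replicate 2 of DMF, 1330 with the compared groups alone (565 rose, 765 fell) and 3840 with normexp correction (2787 rose, 1053 fell). With the filter on all 30 arrays 1413 rose and 645 fell.

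**Figure D3:**
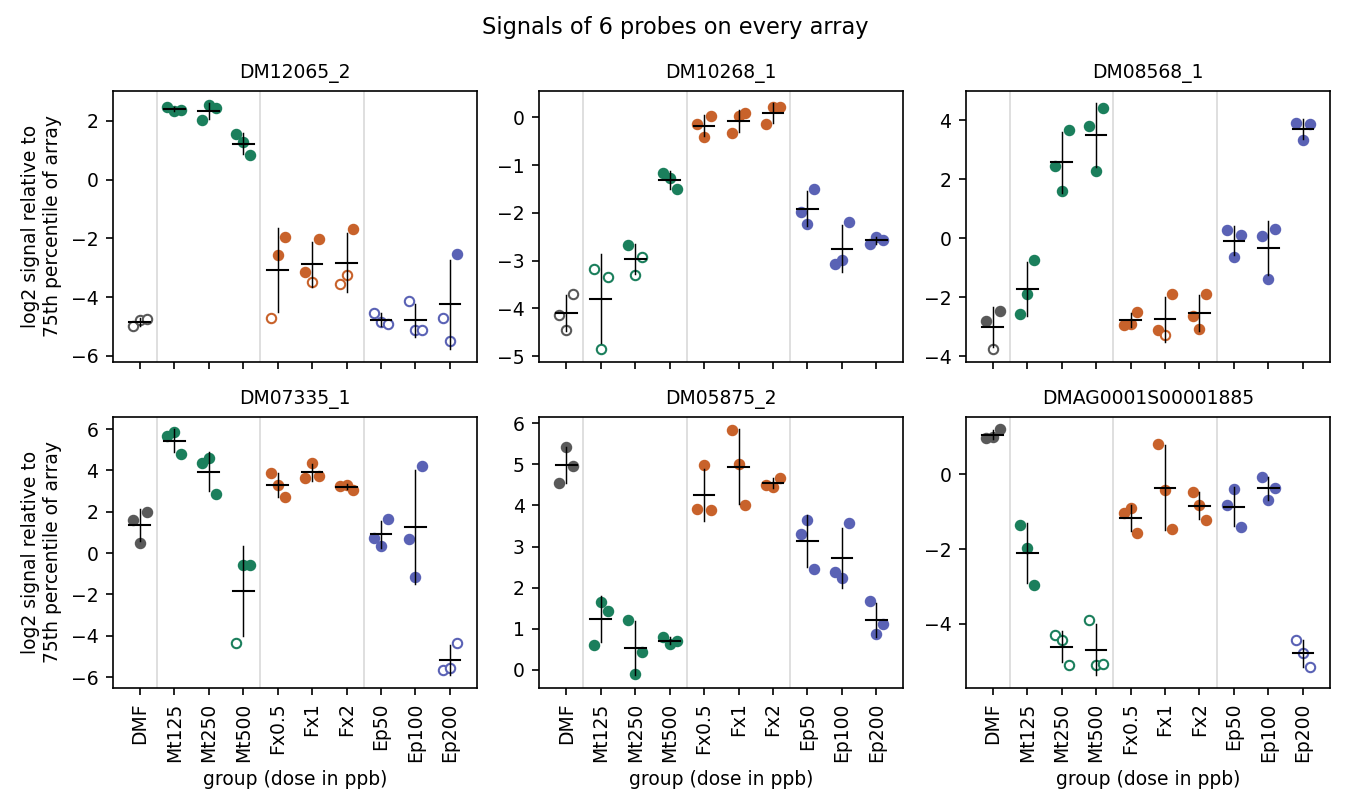
Log2 signal of 6 named probes relative to the array's 75th percentile (vertical axes) on each of the 30 arrays by group (horizontal axes); lines are means, bars are 1 SD over 3 arrays, and open points were not well above background. DM08568_1 lay at 3.50 in Mt500 and 3.70 in Ep200 against -2.53 in Fx2.

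Over the epofenonane doses, 11 probes rose and 3 fell at every dose. DM07102_2 had the steepest rise, at 2.08 ± 0.57 per doubling (adjusted p = 0.032), followed by DM09238_1 at 2.00 ± 0.29 (adjusted p = 0.00018). DM07335_1 and DM07435_2 had the steepest falls, at -3.04 ± 0.49 (adjusted p = 0.00038) and -2.81 ± 0.32 (adjusted p = 1.2e-05). In all, 650 probes had a rising and 671 a falling slope (5.5%), and 557 and 494 of them also had a called slope of the same sign in methoprene, against 12 with a called slope of opposite sign. The 3 epofenonane doses shared slides. With slide as a random block 3009 probes were called and with scan day as a block 2814, and the median slopes within the 3 days were 0.43, 0.31 and 0.44 for rising and -0.76, -0.98 and -0.62 for falling probes. The total of 1321 became 795 and 833 without replicates 1 and 2 of Ep50, 727 without the 3 arrays out of place (414 rose, 313 fell) and 855 with normexp correction (646 rose, 209 fell). With the filter on all 30 arrays 620 rose and 403 fell. DM07102_2 passed no longer without replicates 1 and 3 of Ep50 (adjusted p = 0.082 and 0.18) or replicates 1, 2 and 3 of Ep200 (0.12, 0.072 and 0.078), without a filter (0.056) or with the compared groups alone (0.064). DM07335_1 did not pass with normexp correction (0.18). Over all alternatives their adjusted p ran from 0.0069 to 0.18 and from 6.5e-05 to 0.18.

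The compounds were then compared with each other at their highest doses, which differ in ppb (500, 2 and 200), so that a difference is one between these exposures. None of these groups shared a slide with another, so in these comparisons an effect of the slide cannot be told apart from one of the exposure. Between Mt500 and Fx2, DM08568_1 was higher in Mt500 by 6.03 ± 0.59 on the log2 scale (adjusted p = 5e-07) and DMAG0001S00000312 by 4.82 ± 0.50, at 7.25 ± 0.77 (SD, n = 3) against 2.42 ± 0.59. DM14525_2 and DMAG0001S00004586 were lower in Mt500, by log2 differences of -5.38 ± 1.04 (adjusted p = 0.00077) and -5.07 ± 1.01 (adjusted p = 0.00099). DM10268_1 was lower in Mt500 too (-1.40 ± 0.32, adjusted p = 0.0032), although it rose in both. In all, 2712 probes were higher and 2433 lower in Mt500 (21.3%). A block for the experiment called 8276 probes, with slide as a random block 4153 and with scan day as a block 8139. Within days 2 and 3 the medians were 0.62 and 0.63 for the higher and -0.88 and -1.03 for the lower probes. The total of 5145 became 2042 with the compared groups alone, 2764 with normexp correction and 8330 without a filter (5876 higher, 2454 lower), where the median of all probes stood at 0.14. DMAG0001S00004586 did not pass with the compared groups alone (adjusted p = 0.054, range over all alternatives 0.00075 to 0.054).

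Between Mt500 and Ep200, DM09287_2 and DMAG0001S00005610, which share 1 sequence, were higher in Mt500 by 5.70 ± 0.32 and 5.66 ± 0.31 (adjusted p = 1.6e-10 for both). DM09287_2 lay at 4.73 ± 0.56 (SD, n = 3) in Mt500 and -0.97 ± 0.39 in Ep200, and it had risen in Mt500 and fallen in Ep200 (log2 fold change -1.32 ± 0.32, adjusted p = 0.0093). DM12065_2 was higher in Mt500 by 5.47 ± 0.63. DM09225_1 and DM02156_3 were lower in Mt500, with -2.47 ± 0.36 (adjusted p = 0.0003) and -2.07 ± 0.49 (adjusted p = 0.028). Neither probe was well above background on any Mt500 array, so these sizes rest on signals near background. No difference was called for DM08568_1 (-0.20, 95% interval -1.43 to 1.03) or DMAG0001S00000312 (0.76, -0.26 to 1.79), which leaves differences of that size open. In all, 201 probes were higher and 254 lower in Mt500 (1.9%). The fit with the experiment as a block called 1605 probes, with slide as a random block 255 and with scan day as a block 1662. For the lower probes the medians within days 2 and 3 were -0.61 and -0.81. The total of 455 became 217 without replicate 3 of Mt500, 257 and 217 without replicates 1 and 2 of Ep200, 139 higher and 128 lower without replicate 3 of Ep200, 264 with normexp correction and 12 with the compared groups alone (10 higher, 2 lower). DM02156_3 passed no longer without replicate 3 of Mt500 (adjusted p = 0.2), replicate 1 (0.12) or replicate 3 of Ep200 (0.094), with normexp correction (0.83), slide (0.11) or the compared groups alone (0.4). DM09225_1 did not pass with normexp correction (0.61) or the compared groups alone (0.13). Over all alternatives their adjusted p ran from 0.017 to 0.83 and from 6.8e-05 to 0.61.

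Between Fx2 and Ep200, DM07335_1 and DMAG0001S00004586, with 1 sequence, were higher in Fx2 by 8.38 ± 0.97 and 7.83 ± 1.01, at least 83.3-fold and 77.4-fold. DM07435_2 was higher in Fx2 by 7.24 ± 0.65. DM08568_1 and DM09238_1 were lower in Fx2, with -6.22 ± 0.59 (adjusted p = 2.6e-07) and -4.97 ± 0.59 (adjusted p = 4e-06). In all, 1605 probes were higher and 2082 lower in Fx2 (15.3%). With the experiment as a block 6300 probes were called, with slide as a random block 3280 and with scan day as a block 6206. The lower probes had medians of -0.64, -0.61 and -0.59 within the 3 days. Normexp correction gave 2303, and with the filter on all 30 arrays 990 were higher and 1993 lower.

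How far the compounds changed the same probes was asked from the fold changes themselves. Mt500 and Ep200 shared 1191 probes that rose and 783 that fell, where independent calls would share 159 and 101, a number that takes no account of the shared DMF arrays, and 15 and 3 probes changed in opposite directions. Of the 1191, 33 differed between Mt500 and Ep200 by the test of the difference. Across 24126 probes, which are not independent replicates, the log2 fold changes of Mt500 and Ep200 correlated at r = 0.786, with a covariance of 0.330. Unchanged groups that share 3 controls gave r = 0.467 on average (95% of draws from -0.009 to 0.776) and a covariance of 0.0426 (-0.001 to 0.0974). The r within the 3 experiments was 0.827, 0.734 and 0.594, and r was 0.617 without replicate 1 of Mt500. The 3 controls cannot be split, so part of the excess may come from them. The slopes over dose of methoprene and epofenonane, which use no DMF array, correlated at 0.689.

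Mt500 and Fx2 shared 66 probes that rose, among them DM10268_1. Their fold changes correlated at r = 0.093 (within the experiments 0.090, 0.206 and 0.252), below the simulated mean, and at 0.181 over called probes. The value was 0.335 and 0.266 without replicates 1 and 3 of DMF. Fx2 and Ep200 shared 20 probes that rose, and 16 rose in Fx2 and fell in Ep200. Their r was -0.073 (within the experiments 0.006, 0.129 and 0.178), -0.276 over called probes, and 0.260 and 0.077 without replicates 1 and 3 of DMF, so its sign rested on single control arrays. At the lowest doses Mt125 and Fx0.5 shared 56 probes that rose, and their r was 0.754 (within the experiments 0.731, 0.688 and 0.609), which lies inside the range that shared controls gave without any change (-0.009 to 0.776). Their covariance was 0.178, above the simulated range (-0.001 to 0.0974). Another 24 probes that rose in Fx0.5 fell in Mt125. The 79 probes that rose at all 3 fenoxycarb doses had medians of 0.47, 0.59 and 0.92 in the methoprene groups by dose, with 33 risen and 24 fallen at Mt125 and 53 risen at Mt500. In Ep200 their median was 0.09, with 19 risen and 12 fallen.

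**Figure D4:**
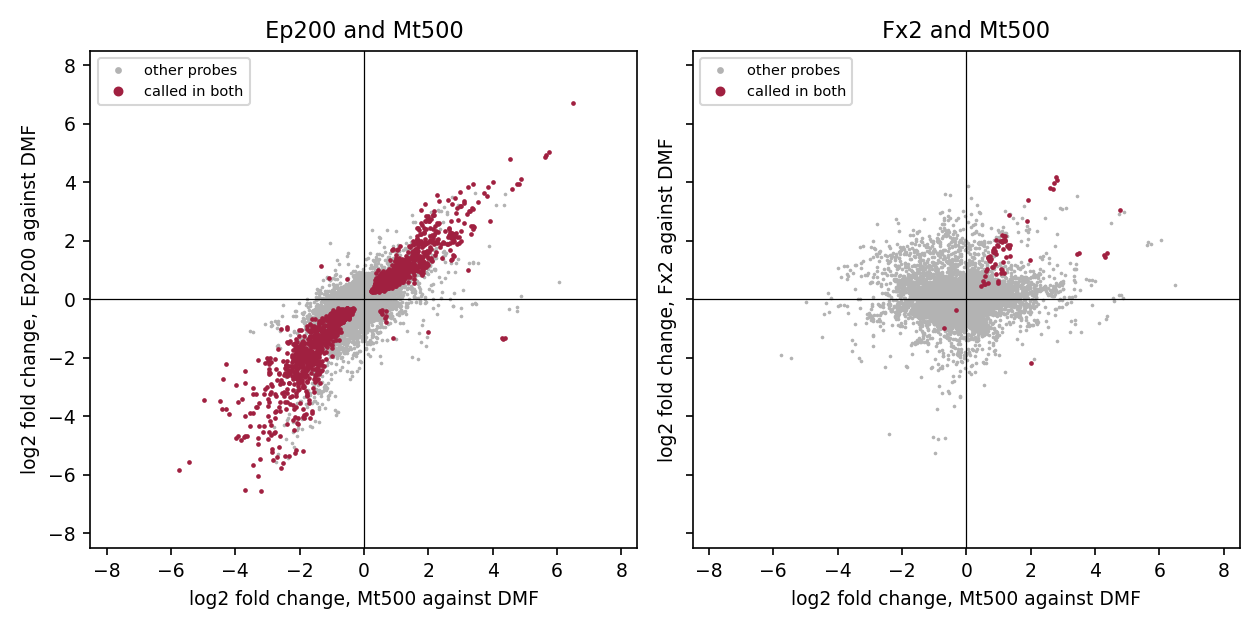
Log2 fold change against DMF of each of 24126 probes in Mt500 (horizontal axes) and in Ep200 (left, vertical axis) or Fx2 (right, vertical axis), with probes called in both comparisons in dark red. The correlation was 0.786 on the left and 0.093 on the right.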

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

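Tests chosen after the result was seen were those of array exchange, of RNA from another experiment, of overall signal, of shared DMF arrays and of slide through the dose slopes for Mt500 and Ep200, and of labelling batch, scan day (both tests of each) and moult stage for the first component. The other tests in this part were fixed before their results.

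Some probes were called in opposite directions at doses of 1 compound and at doses of different compounds. Mt125 and Mt500 shared no slide, nor did Fx2 and Ep200, so the slide cannot be told apart from the exposure here. Every probe called in opposite directions in the pairs below also had a called slope or difference, so that condition removed none and adds no support. Of the probes, 149 rose at Mt125, fell at Mt500 and had a falling slope over the methoprene doses, and 34 fell at Mt125, rose at Mt500 and had a rising slope. Independent calls would give 76.6 and 71.4 such probes, and 4.3 and 0.86 for Fx2 and Ep200 below. These numbers take no account of the shared DMF arrays. Between Fx2 and Ep200, 16 probes rose in Fx2 and fell in Ep200 with a called difference, among them DM06982_1 (1.84 and -1.52) and DM09287_2 (1.59 and -1.32). The reverse held for 3 probes: DM03726_3 (-0.93 and 0.83, difference -1.77 ± 0.21 SE), DM04512_2 (-0.48 and 0.40, difference -0.87 ± 0.11) and DM07400_1 (-2.18 and 2.69, difference -4.87 ± 0.48). The fall of DM07400_1 in Fx2 passed no longer in 9 of 16 alternatives, with an adjusted p by limma of up to 0.33. DM03726_3, DM04512_2 and DM06982_1 were chosen after their values were seen.

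For each comparison the 6 arrays compared (for a slope, those of the lowest and highest dose) were regrouped in 10 ways, the real one included, which is too few for a share under 0.05. In 14 comparisons 1 of the 10 splits, the real one, called as many probes as the real one. The real count and the highest of the other splits were 1460 and 0 for Mt125, 1667 and 0 for Mt250, 4918 and 1 for Mt500, 112 and 0 for Fx0.5, 133 and 0 for Fx1, and 113 and 0 for Fx2. They were 41 and 0 for Ep50, 148 and 3 for Ep100 and 2530 and 1 for Ep200, each against DMF by limma. For the slopes they were 4441 and 0 for methoprene and 1321 and 1 for epofenonane. Between compounds they were 5145 and 0 for Mt500 and Fx2, 455 and 5 for Mt500 and Ep200, and 3687 and 0 for Fx2 and Ep200. For the fenoxycarb slope all 10 splits called 0 probes. In the 11 comparisons where the experiment number pairs the arrays, the other splits that part all 3 pairs called 0 probes by limma.

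The fold changes of Mt500 and Ep200 went together (r = 0.786 across probes, where unchanged groups with shared controls gave -0.009 to 0.776). A lower overall signal at the highest doses stays open: the mean 75th percentile was 61.5 ± 7.10 (SD, n = 3) for Ep200 and 59.7 ± 5.46 for DMF, a difference inside their spread, and 50.3 ± 2.62 for Mt500. Shared DMF arrays, and the slide, were argued against as the whole cause by the dose slopes, which use no DMF array and, for epofenonane, cancel the slides: their r was 0.689, and the middle 95% of simulated unchanged contrasts ended at 0.573. A stricter test with both contrasts within slides gave r = 0.358, below its own simulated limit of 0.577, so on it the slide cannot be told apart from the dose, with 2 slides for the methoprene contrast. A shared response of the animals to the highest doses stays open, as a hypothesis found and tested on the same arrays.

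The fold changes of Mt125 and Fx0.5 had r = 0.754 across probes, inside the range of -0.009 to 0.776 that unchanged groups with shared controls gave, and a covariance of 0.178, above the simulated range of -0.001 to 0.0974. Shared DMF arrays and slide were argued against as the whole cause by 2 contrasts within slides that share no array, Mt125 against Ep50 and Ep100 and Fx0.5 against DMF, with r = 0.656 where the middle 95% of simulated values ended at 0.488. That contrast takes epofenonane arrays as its reference, and when Mt250 was the reference r was 0.446, below the simulated 0.573. A part played by the epofenonane arrays therefore cannot be told apart from a shared response of the animals. Mt250 shares its compound with Mt125, which keeps this second test open.

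The first component, with 38.8% of the variance, had 27 of the 30 arrays on the side of their experiment (1 against 2 and 3). Replicate 1 of Mt250, replicate 2 of Ep50 and replicate 1 of Ep100 lay on the other side. An exchange of labelled RNA, arrays or scans was argued against for these 3 arrays, as was the labelling batch as their source: they had the spike-in signal over background of the experiment in their label (82.5, 41.9 and 79.5, with 75.5 to 88.7 in experiment 1 and 36.2 to 48.4 in experiments 2 and 3), while for the other 27 arrays the labelling batch cannot be told apart from the experiment. Scan day also had 27 arrays with it and 3 against it (replicate 1 of Mt500, replicate 2 of Ep50 and replicate 1 of Ep100), so it was not the whole source, but it cannot be told apart from the experiment number, since of the 2 arrays where they part 1 (Mt500) lay with its experiment and 1 (Mt250) with its day. RNA of another experiment labelled under this number also stays open: the SD of the log2 difference to the array of the same group that each of the 3 resembles was at most 0.416, against 0.505 to 1.16 within the other 7 groups, but different RNAs of 1 experiment came as close as 0.295 and no RNA was hybridised to 2 arrays. The 5 probes with the cuticle motif had a mean r of 0.903 with the component, while the middle 95% of random lists of like signal ended at 0.189. Those lists were drawn probe by probe, so their limit is too narrow for probes that vary together. A difference in moult stage between the experiments stays a hypothesis that this test cannot decide.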

How the results depend on the processing

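The fit without the 3 arrays out of place was chosen after the components were seen. The motif classes were chosen after the annotation columns were seen and before any test on them was run. Of the 56 named calls, each under the other settings that gave it a value, 461 results kept their direction and passed and 48 kept their direction without passing, and on leaving out 1 array 276 and 60 did so. None turned direction. On leaving out 1 array none could, since the rule named only probes whose 3 arrays all lay on 1 side of the other 3. The kept direction therefore adds no support there, and only the passing or not passing is informative. The filter on all 30 arrays left out the probes of 45 of the 56 and the series table gave no value for 6. Counts stayed within 1.5 times in 90 cases and moved in 60 under other settings. Quantile normalization and the values of the series table moved none of the 15 counts by more than 1.5 times. The series table holds the same processed signal. Relative to DMF, its array constants differed from the percentiles subtracted in the main fit by at most 0.023 log2 units. Its counts could therefore hardly move, and they are no independent check. The fenoxycarb slope had 0 calls by limma under every setting (176 at an unadjusted p below 0.05, fewer than would pass with no slope). Signal over background limits what can be seen, with 48.0% to 57.7% of probes well above background on an array. The self-test, with noise independent between probes, found 13.1%, 54.9% and 87.0% of simulated changes of 0.5, 1 and 2 log2 units. The fixed gene lists could not be matched to probes and were not run. The causes of the moves below were not tested, except that fewer arrays enter a fit of the compared groups alone.

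With the experiment as a block, the counts against DMF were 3318 for Mt125, 3533 for Mt250, 7987 for Mt500, 235, 449 and 241 for Fx0.5, Fx1 and Fx2, and 126, 561 and 4927 for Ep50, Ep100 and Ep200. They were 7306 and 2872 for the methoprene and epofenonane slopes, 8276 for Mt500 and Fx2, 1605 for Mt500 and Ep200 and 6300 for Fx2 and Ep200. For Mt250, Ep50, Ep100 and the epofenonane slope the arrays of 1 number did not correlate in each experiment, so a call gained or lost there says nothing of the size of an effect. By the correlation of their deviations from the group mean, 28 of 30 arrays best matched an array of their own number outside their group, which is a hint only. Replicate 2 of Ep50 and replicate 1 of Ep100 were the exceptions, while replicate 1 of Mt250 was among the 28. With scan day as a block the counts, in the same order, were 3245, 3538, 7824, 227, 430, 243, 120, 562, 4796, 7290, 2814, 8139, 1662 and 6206. With slide as a random block they moved to 274 for Fx0.5, 524 for Fx1, 336 for Fx2, 13 for Ep50, 83 for Ep100, 3009 for the epofenonane slope and 255 for Mt500 and Ep200.

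With the compared groups alone they moved to 727 for Mt125, 404 for Mt250, 1222 for Mt500, 47 for Fx0.5, 0 for Ep50 and Ep100, 1330 for Ep200, 2306 for the methoprene slope, 2042 for Mt500 and Fx2 and 12 for Mt500 and Ep200. Normexp correction moved them to 2718 for Mt500, 27 for Ep50, 3840 for Ep200, 2572 and 855 for the methoprene and epofenonane slopes, 2764 for Mt500 and Fx2, 264 for Mt500 and Ep200 and 2303 for Fx2 and Ep200. The filter on all 30 arrays gave 74 for Fx0.5 and 84 for Fx1, and no filter gave 8330 for Mt500 and Fx2. Without the 3 arrays they moved to 998 for Mt250, 19 for Ep50, 42 for Ep100 and 727 for the epofenonane slope. Without the 3 arrays and with the experiment as a block, these counts were 2479, 37, 200 and 1878. Over called probes the agreement moved to 0.181 for Mt500 and Fx2 and -0.276 for Fx2 and Ep200.

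On leaving out 1 array at a time the counts ran from 674 to 1633 for Mt125, 952 to 1462 for Mt250, 3476 to 4813 for Mt500, 50 to 94 for Fx0.5, 77 to 122 for Fx1, 68 to 81 for Fx2, 18 to 34 for Ep50, 57 to 100 for Ep100 and 1663 to 2359 for Ep200. For the slopes they ran from 3200 to 4432 for methoprene and 795 to 1072 for epofenonane, and between compounds from 3562 to 4904 for Mt500 and Fx2, 217 to 645 for Mt500 and Ep200 and 2605 to 2976 for Fx2 and Ep200. The agreement ran from 0.617 to 0.831 for Mt500 and Ep200, 0.058 to 0.335 for Mt500 and Fx2 and -0.093 to 0.260 for Fx2 and Ep200.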

Other observations

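The classes of protein motif below were chosen after the annotation columns were seen and before any test on them was run, and the test of the cuticle motif against the array out of place was fixed before its result. Of 9 probes whose sequence encodes conserved ubiquitin peptides, 8 rose and 1 (DM01643_2, -0.73, read on the complement strand) fell at Mt500, 4 rose at Mt250, 1 at Mt125 and 4 at Ep200. Those that rose at Mt500 carry only the numbers DM00737, DM01627 and DM01791, so they are repeat probes and not separate members of the class. The set test used the 8 of the 9 probes with no missing spot, which leaves out DM01791_3 and keeps DM01643_2. Their mean log2 fold change at Mt500 was 0.57 ± 0.53 (SD over probes, adjusted p = 1.1e-05), but the call was lost with an estimated correlation (adjusted p = 0.11). At Mt250 the mean was 0.37 (adjusted p = 1.6e-05, and adjusted p = 0.12 with an estimated correlation), at Mt125 0.19 (0.022, and 0.81) and at Ep200 0.30 (0.0066, and 0.57). The adjusted p at Mt125 was 0.16 with quantile normalization and 0.11 with the series table, and at Ep200 0.08 with quantile normalization. DM01627_1 rose by 0.77 ± 0.09 (SE, n = 3) at Mt500 and 0.44 at Ep200. At the fenoxycarb doses the class was not called (adjusted p = 0.11 at Fx2).

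The 2 probes with the catalytic motif of chitinases, enzymes that break down chitin, rose at the higher methoprene doses and at Ep200. DM00952_2 and DM00952_3 rose by 1.31 and 1.39 ± 0.15 (SE, n = 3, adjusted p = 8.3e-07 for the latter) at Mt500, by 0.55 and 0.66 at Mt250 and by 0.85 and 1.00 at Ep200. At Fx2 their log2 fold changes were 0.15 and 0.29 and did not pass. A class of 2 probes was too small for the set test, and both carry the number DM00952. The classes of thioredoxin (8 probes, adjusted p = 0.23 at Mt500), trypsin-like proteases (14 probes, 0.94 at Mt500) and carboxylesterases or lipases (5 probes, 0.94 at Mt500) were not called as classes at any dose. The set test looks for a shift in 1 direction, and single trypsin-like probes were called both ways. Of these, 1 rose and 2 fell at Mt125, and 2 rose and 1 fell at Mt500. At Mt500 2 thioredoxin probes fell.

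The 5 probes with the cuticle motif, a chitin-binding sequence, had a mean log2 fold change of -2.20 ± 1.07 (SD over probes) in Ep50 (adjusted p = 0.014, and adjusted p = 0.66 with an estimated correlation), with 0 of them called alone by limma. In the 2 other groups with an array out of place the mean was positive and not called, at 1.97 ± 1.34 in Ep100 (adjusted p = 0.33) and 1.62 ± 1.14 in Mt250 (adjusted p = 0.74). Without replicate 2 of Ep50 the mean in Ep50 was -1.55 ± 0.77, and with experiments 1 and 3 alone -0.90 ± 0.44. Their mean log2 signal was -2.42 ± 0.44 (SD, 8 arrays) in experiment 1, 2.08 ± 0.48 (9 arrays) in experiment 2 and 2.86 ± 0.93 (10 arrays) in experiment 3. The 3 arrays out of place had 2.68 (replicate 1 of Mt250), -2.35 (replicate 2 of Ep50) and 3.26 (replicate 1 of Ep100). The pattern for collagen matched 8 probes and as many reversed sequences. Repeats of glycine and proline codons read as such repeats when reversed too, so that count cannot tell whether the matches came by chance. Its result in Ep50 (-2.20, adjusted p = 0.014 by camera) was lost with an estimated correlation (adjusted p = 0.66) and is not interpreted.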
